A study of Homo sapiens with 4 samples.

How the data were processed

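Expression was measured in 4 samples of total RNA from the established human cell line P493-6, of which 2 were labelled as hypoxia and 2 as non-hypoxia. Per the labels' protocols, hypoxic cells were held in a chamber at 0.1% oxygen for 29 hours, the other cells at 20% oxygen, RNA was extracted with Trizol, and it was amplified in a single round from an oligo-dT primer carrying a T7 promoter and labelled with biotin. Per the file headers, the arrays were Affymetrix HG-U133 Plus 2, a design of short oligonucleotides in which a probe set reads 1 transcript or a few related ones.

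The deposited values are signal intensities on a linear scale, 1 per probe set and array, made with GCOS 1.1.1 and MAS5 per the submitters' processing notes, which do not give their roles. MAS5 subtracts background and combines the probes of a probe set on each array alone. In the deposited table the mean signal without the lowest and highest 2% of probe sets was 150.0 on all 4 arrays, so each array had been scaled to the same target. A change in the total amount of messenger RNA per cell can therefore not be seen, and genes are read relative to the rest. The medians were 47.1 and 47.1 on the hypoxic arrays and 47.2 and 41.7 on the normoxic arrays, and values ran from 0 to 17877. Detection calls were not used here. The number of arrays, 2 per group, limits the precision.

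Probe sets were named from the platform's annotation, with symbols updated through the gene identifier in the RefSeq gene table of assembly GRCh38.p14. Of 54613 probe sets that are not controls, 41091 carried 1 gene symbol, of which 41037 matched that table by identifier, 1801 carried several and 11721 none, and the last 2 kinds were left unnamed. No coordinates are given because no genome build is named for the deposited values.

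Signals were tested as log2(signal + 16) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend on signal), hypoxia against normoxia, two-sided, on all 4 arrays without covariates. Fold changes are on the log2(signal + 16) scale, which understates the changes of dim genes. The 62 control probe sets were left out, as were the 50% of probe sets with the lowest mean over the 4 arrays, which left 27306 probe sets and a residual of 2 degrees of freedom with a prior of 5.42. For genes, the brightest tested probe set stood for each of 12402 genes, with a prior of 5.92. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. An exact permutation test of a single gene cannot go below p = 0.333 with 2 against 2. Of 5660 genes with more than 1 tested probe set, 798 were called. In the fit of probe sets, 222 of these had more than 1 probe set called in the same direction and 4 had a probe set called in the opposite direction. The 222 can miss genes whose brightest probe set passed only in the fit of genes.

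Before the data were examined, 37 gene lists were written, holding 1029 different genes, of which 924 had a probe set naming them alone and 850 were tested. The 36 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01 and adjusted over the lists. The list of erythroid markers had 2 tested members and no test. Camera was also run with an estimated correlation, which rests on 2 residual degrees of freedom. Genes named in the text were chosen by a rule fixed at the same time: a panel of 11 genes, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, up to 4 members of each list with the smallest p, and the control probe sets for actin and GAPDH. The groups of all 1385 called genes did not overlap, and 55.9% of tested genes did not overlap where chance gives 33.3%. CA9, 1 of the panel, was not analysed here. Further genes are marked where they were named after their values were seen.

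The fit was tested on simulated data of the same size, in 5 runs with 200 changed genes among about 12408. Of simulated changes of 1.5-fold, 44.2% were called, of 2-fold 80.3% and of 4-fold 98.2%, and 6.70% of the calls were false. A list of genes shifted together was found in 5 of 5 runs, and at most 1 of 36 unshifted lists was called in a run. The spread of each simulated probe set came from the main fit, so the runs assume its variance model and cannot test it. The changed genes were also fewer than the 1385 called in the data. The noise was drawn independently for each probe set, so the runs cannot show how often lists of correlated genes are called falsely. In the data the estimated correlation within a list reached 0.60, for cytosolic ribosomal proteins.

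The alternatives were an offset of 1 or 64, no filter or a filter at the 75th percentile, median centring, quantile normalization, no variance trend, the replicate number as a block, each array left out in turn, and the mean of a gene's probe sets. Camera with an estimated correlation was planned as well. Ranges and counts over the alternatives leave it out, and with it no list passed (lowest adjusted p = 0.386). A fit without probe sets whose names end in _x_at, which can bind several transcripts, and the mean of probe sets for single named genes were added after seeing the data. The labels number the samples 1 and 2 in each group but do not say that a number marks a shared culture or day, so the main fit has no block. In each fit of genes the brightest probe set was picked anew, so a gene's value in an alternative can come from another probe set. With 1 array left out, the remaining array of that group is assumed to vary like the other group. The spread then rests on the other group alone, so a call can be lost at an unchanged fold. Figures were drawn with matplotlib 3.10.9.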

Results

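Gene expression was measured in P493-6 cells, a human B lymphocyte line that the submitters label as Burkitt's lymphoma and that is used as a model of growth driven by the transcription factor MYC. Cells kept at 0.1% oxygen for 29 hours were compared with cells kept at 20% oxygen, to find the genes that respond to hypoxia. The duration was chosen by the submitters for its high level of HIF-1, the transcription factor stabilised in low oxygen. Each group held 2 samples, each read on its own Affymetrix HG-U133 Plus 2 array with 54675 probe sets. Nothing in the labels says whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value. Across the 27306 tested probe sets, the log2 signals of the hypoxic arrays correlated with each other at r = 0.975 and those of the normoxic arrays at r = 0.974, while arrays of different groups correlated at 0.953 to 0.958. These coefficients are across probe sets, which are not independent replicates.

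Low oxygen changed the level of many transcripts, and genes of glucose metabolism, oxygen sensing and the hypoxia response were among those with the largest rises. Of 12402 genes tested, 579 rose and 806 fell, and the change was at least 2-fold in 150 of those that rose and 80 of those that fell. The larger number of falls did not hold without normoxia replicate 2, where 614 genes rose and 512 fell, without hypoxia replicate 2 (195 and 185) or without a variance trend (119 and 68). On the log2(signal + 16) scale, the largest rises were in IGFBP2, an insulin-like growth factor binding protein, at 13.0-fold, EGLN1, an oxygen-sensing prolyl hydroxylase that marks HIF-1 alpha for degradation, at 12.5-fold, and PFKFB4, which makes the glycolytic activator fructose 2,6-bisphosphate, at 10.7-fold. They were followed by HILPDA (9.93-fold), PDK1 (9.58-fold), FABP6 (8.88-fold), PPFIA4 (8.21-fold), POFUT4 (6.91-fold), VEGFA (5.81-fold) and HK2 (5.72-fold). The largest falls were in PABPC1L (5.21-fold), the immediate early transcription factor EGR1 (4.56-fold), CARD16 (4.33-fold), the heat shock protein HSPH1 (3.80-fold) and CDC20, an activator of the anaphase-promoting complex (3.53-fold). CDK5 (3.46-fold), ANXA4 (3.14-fold), MPND (3.09-fold), CAPN10 (3.05-fold) and HACD4 (2.97-fold) came next. Among these 20 genes the smallest standard error was that of HILPDA, with a log2 fold change of 3.31 ± 0.09 (SE, limma, adjusted p = 6.70e-06), and the largest that of FABP6, at 3.15 ± 0.53 (adjusted p = 0.010).

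Calls were made with limma at a Benjamini-Hochberg adjusted p under 0.05. In probe sets, 851 rose and 950 fell, but more rose than fell without any 1 of the 4 arrays (808 and 500 without normoxia replicate 2). With each array centred on its median instead, the split was 666 to 1180 for probe sets and 461 to 975 for genes. Far fewer genes were called without either hypoxic array, where the spread is taken from the normoxic arrays alone. The number was 187 when the variance was not modelled as a function of signal. In that fit, 71 of the 120 named genes past the threshold lost their calls. Folds of genes with a low signal in either group, and so their rank, depend on the offset added before the log. With offsets of 1 and 64, the log2 fold change was 4.14 and 2.76 for EGLN1, 4.14 and 2.14 for FABP6, 3.79 and 2.02 for PPFIA4, -2.47 and -1.49 for CARD16, -2.40 and -1.03 for CDK5, -2.09 and -0.99 for MPND, and -2.17 and -0.91 for CAPN10. The mean over a gene's probe sets, applied to single genes after the data were seen, gave smaller values for PDK1 (2.52), VEGFA (1.85) and EGR1 (-1.38). FABP6 was at 2.16 without normoxia replicate 1 and 4.14 without normoxia replicate 2, and it lost its call without hypoxia replicate 1 (adjusted p = 0.0767) or hypoxia replicate 2 (adjusted p = 0.0518), as did CDK5 and CAPN10 without hypoxia replicate 1 (adjusted p = 0.0509 for each). PABPC1L rested on 1 of its 3 probe sets, and its call was lost over the mean of them (-0.88, limma, adjusted p = 0.0565). With an offset of 1 its value was -0.49 (adjusted p = 0.358). A smaller offset enlarges the fall of the called probe set, so that value was read from another one. The log2 fold change of PABPC1L was -0.48 without normoxia replicate 1 and -0.31 without normoxia replicate 2, where another of its probe sets was the brightest too.

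**Figure D1:**
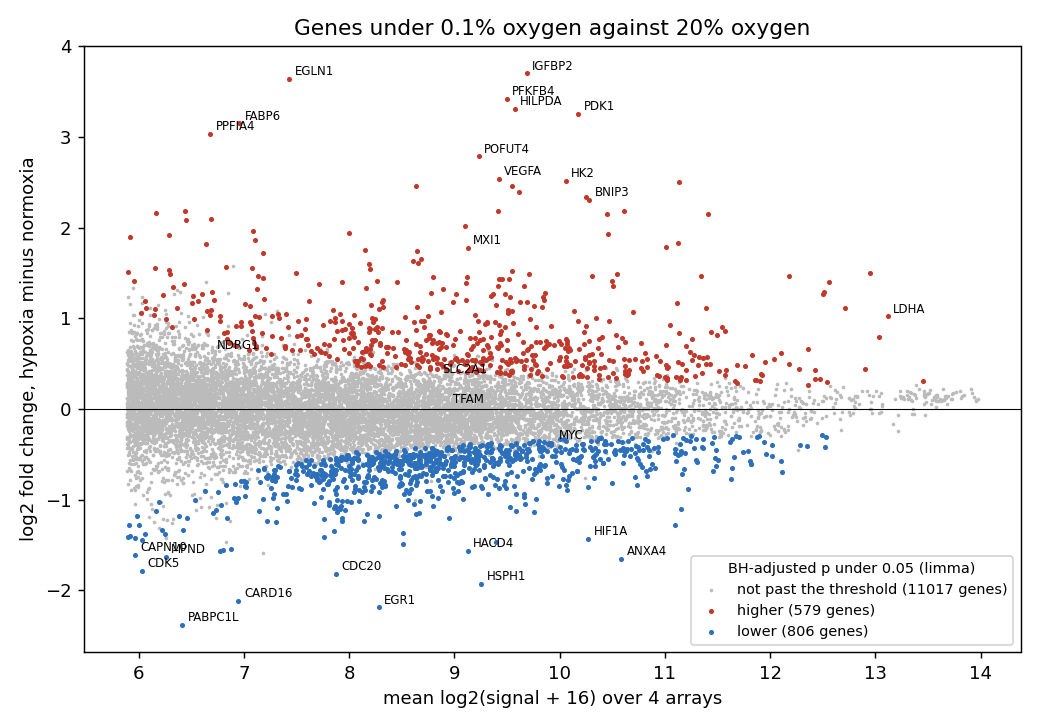
Log2 fold change of hypoxia over normoxia (vertical axis, log2 units) against the mean log2 signal over the 4 arrays (horizontal axis), with 1 point for each of the 12402 genes. The 579 genes that rose are red, the 806 that fell are blue, and the fixed panel and the 10 largest changes in either direction are named. IGFBP2, EGLN1, PFKFB4, HILPDA and PDK1 lie furthest above 0.

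Most measured genes of glycolysis rose. Of 20 genes on the list for glycolysis and lactate export, 17 rose, none fell and 3 did not pass the test (19 rose when adjusted over the list alone). Hexokinase HK2, which commits glucose to metabolism, rose from a mean signal of 430.5 ± 49.9 to 2537 ± 237 (SD, n = 2 arrays per group). Glucose phosphate isomerase GPI rose 3.46-fold, the aldolase ALDOC 3.83-fold and phosphoglucomutase PGM1, which links glycogen to glycolysis, 4.54-fold. LDHA, which reduces pyruvate to lactate, rose 2.03-fold from an already high signal of 6211 ± 210 to 12655 ± 969 (SD, n = 2; limma, adjusted p = 2.90e-04). The genes that did not pass were GAPDH (log2 fold change 0.26) and PFKM (0.25), both named after their values were seen, and the glucose transporter SLC2A1 (0.36 ± 0.20 SE, adjusted p = 0.309). Outside the test, the control probe sets for GAPDH were higher in hypoxia by 0.42 to 0.49. Their signals lie near the highest on the arrays, where differences may be compressed, so a rise of GAPDH is not excluded. SLC2A1 depended on the normoxic arrays, with 0.68 (adjusted p = 0.0164) without normoxia replicate 1 and 0.03 (adjusted p = 0.937) without normoxia replicate 2, and it passed in no other alternative. The list had a median log2 fold change of 1.42 (camera, adjusted p = 9.57e-27 over 36 lists), with an adjusted p = 0.386 with an estimated correlation between genes.

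At the step where pyruvate enters mitochondria, 2 kinases that switch off pyruvate dehydrogenase rose. PDK1 rose from 361.8 ± 73.3 to 3568 ± 22.9 (SD, n = 2), a log2 fold change of 3.26 ± 0.13 (SE, limma, adjusted p = 2.07e-05), and all 3 of its tested probe sets rose. PDK3 rose 1.85-fold (adjusted p = 0.00512), on 1 of its 5 tested probe sets. The other 12 of the 14 measured genes on this list did not pass (2 rose and none fell when adjusted over the list alone), among them DLAT, a subunit of pyruvate dehydrogenase, with a log2 fold change of -0.31, and the lactate dehydrogenase subunit LDHB, with 0.22. The list as a whole did not pass (camera, adjusted p = 0.483). PDK1 stood in the panel because the study that made these arrays is known for it, so its rise here is not independent evidence.

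Among established hypoxia markers outside glycolysis, 33 of 39 measured genes rose, 1 fell and 5 did not pass (37 rose and 1 fell when adjusted over the list alone). The angiogenic factor VEGFA rose from 271.2 ± 59.3 to 1636 ± 16.8 (SD, n = 2), with all of its 4 tested probe sets past the threshold. The mitophagy receptors BNIP3 and BNIP3L rose 4.96-fold and 3.56-fold, and MXI1, an antagonist of MYC, rose 3.43-fold. FAM162A rose 4.43-fold and the adenylate kinase AK4 4.45-fold. The gene that fell was the transferrin receptor TFRC (log2 fold change -0.31), named after its value was seen, and NDRG1 was among those that did not pass (0.62 ± 0.21 SE, adjusted p = 0.0971). TFRC lost its call without hypoxia replicate 1, hypoxia replicate 2 or normoxia replicate 2 (adjusted p = 0.193, 0.152 and 0.177). Over the whole list, the median log2 fold change was 1.36 (camera, adjusted p = 4.49e-38), with an adjusted p = 0.386 with an estimated correlation.

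Components of the oxygen-sensing pathway moved in opposite directions. The transcript of HIF1A, which encodes the oxygen-regulated subunit of HIF-1, fell 2.70-fold, from 2018 ± 30.8 to 737 ± 26.9 (SD, n = 2; limma, adjusted p = 1.08e-04), as read by the single probe set that names it. The prolyl hydroxylases EGLN1 and EGLN3 rose 12.5-fold and 3.30-fold. The coactivator CREBBP rose 1.29-fold, a call lost without hypoxia replicate 1, hypoxia replicate 2 or normoxia replicate 2 (adjusted p = 0.251, 0.135 and 0.121), with median centring (0.199), no filter (0.0831) or the mean of probe sets (0.137). Of 14 measured genes on the list of HIF pathway components, 3 rose, 1 fell and 10 did not pass (5 rose and 1 fell when adjusted over the list alone). The list did not pass as a whole (camera, adjusted p = 0.0862, and 0.546 with an estimated correlation). It passed only without normoxia replicate 1, where its median log2 fold change was 0.25 against 0.14 with all arrays. At the preset correlation the adjusted p ran up to 0.314 over the alternatives.

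**Figure D2:**
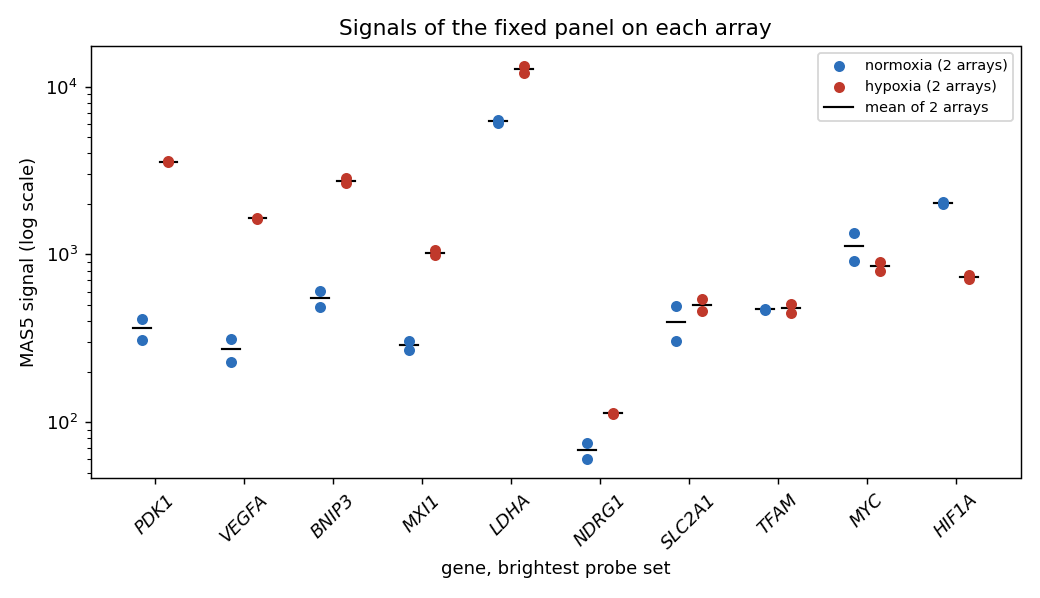
MAS5 signal (vertical axis, log scale) of the 10 measured genes of the fixed panel on each array, with 2 normoxic arrays in blue, 2 hypoxic arrays in red and black bars at the group means. PDK1, VEGFA, BNIP3, MXI1, LDHA and NDRG1 are higher on both hypoxic arrays, and HIF1A and MYC are lower on both. Of these, NDRG1 and MYC did not pass the test. The normoxic values of MYC and of SLC2A1 lie far apart.

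Part of the genes of mitochondrial energy metabolism fell. In respiratory chain complex I, the entry point of electrons from NADH, 9 of 33 measured subunits fell, none rose and 24 did not pass (13 fell when adjusted over the list alone). NDUFS7 fell 1.80-fold and NDUFB5 1.51-fold. Cytochrome c (CYCS) fell 1.38-fold, the only call among 33 measured genes on the list for complexes III to V (1 also when adjusted over the list alone). It carries electrons between complexes and is not a subunit of them, so no subunit on that list was called. Of 17 measured genes on the list for the tricarboxylic acid cycle, 5 fell and none rose (5 fell and 3 rose when adjusted over the list alone). Those that fell included the isocitrate dehydrogenase subunit IDH3A (1.81-fold) and the succinyl-CoA ligase subunit SUCLA2 (1.57-fold). Also counted was IDH1 (1.36-fold, on 1 of its 3 probe sets), a cytosolic enzyme outside the mitochondrial cycle. The complex I list had a median log2 fold change of -0.15 (camera, adjusted p = 0.010), with an adjusted p = 0.759 with an estimated correlation. The lists for complexes III to V and for the tricarboxylic acid cycle did not pass (adjusted p = 0.424 and 0.695). Over the mean of their probe sets, the calls of IDH3A (-0.37, limma, adjusted p = 0.251; 1 of its 3 probe sets passed) and CYCS (-0.24, 0.235; 1 of 2) were lost. Calls were also lost with 1 array left out, where the spread rests on the other group alone and a call can go at a similar fold. CYCS was at -0.49 without hypoxia replicate 1 and -0.44 without hypoxia replicate 2, against -0.46 with all arrays. SUCLA2 moved more, to -0.51 without hypoxia replicate 2 against -0.65. The complex I list lost its call without hypoxia replicate 1 (adjusted p = 0.120), without normoxia replicate 2 (0.135, median -0.01) and with the filter at the 75th percentile (0.0654), within a range of 1.15e-04 to 0.135 over the alternatives, and 1 subunit fell without either hypoxic array and 3 without normoxia replicate 2. Without hypoxia replicate 1, calls were lost for NDUFB5 (adjusted p = 0.0639) and CYCS (0.0785), and 2 cycle enzymes fell. Without hypoxia replicate 2, they were lost for NDUFS7 (0.0569), CYCS (0.0953), IDH3A (0.0511) and SUCLA2 (0.115), and 1 cycle enzyme fell. Without normoxia replicate 2, 3 cycle enzymes fell and 1 rose, and without normoxia replicate 1, 4 fell and 1 rose. UQCRQ of complex III fell as well without normoxia replicate 1 (log2 fold change -0.39), under quantile normalization (limma, adjusted p = 0.0406) and with the replicate block. On the same list, UQCRB fell in 5 of 14 alternatives, among them quantile normalization (0.0341) and the mean of probe sets (0.0360), and ATP5F1E in 3.

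Of 67 measured mitochondrial ribosomal proteins, 9 fell and 1 rose (10 and 2 when adjusted over the list alone), among them MRPL34 (2.23-fold lower) and MRPL19 (2.06-fold lower). MRPL19 passed on 1 of its 3 probe sets and lost its call over the mean of them (-0.47, limma, adjusted p = 0.0795). The list lay just outside the threshold (camera, adjusted p = 0.0508) and passed in 6 of 14 alternatives, which were without normoxia replicate 1 (0.00201), an offset of 1 (0.0474), no filter (0.00669), median centring (0.0381), the replicate block and the fit without _x_at probe sets (0.0376), within a range of 0.00201 to 0.400. The number that fell was 2 without hypoxia replicate 1, hypoxia replicate 2 or normoxia replicate 2, and 12 without normoxia replicate 1. In the fit without normoxia replicate 2, 2 rose, and none rose in the other 3. On the list for mitochondrial biogenesis and import, 2 of 28 measured genes rose and none fell (2 also when adjusted over the list alone), the import receptor TOMM20 (1.44-fold) and the protease LONP1 (1.42-fold). Both lost their calls without hypoxia replicate 1 (adjusted p = 0.0823 and 0.124) or hypoxia replicate 2 (0.152 and 0.193), LONP1 also without normoxia replicate 1 (0.0892), and TOMM20 also over the mean of its probe sets (0.37, adjusted p = 0.0511). On that list 1 rose and 1 fell without normoxia replicate 1, and 3 rose without normoxia replicate 2. TFAM, a transcription factor of the mitochondrial genome, had a log2 fold change of 0.02 ± 0.11 (SE, limma, adjusted p = 0.922), and that list did not pass (camera, adjusted p = 0.962).

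Some DNA replication genes rose and some mitosis genes fell. Of 43 measured DNA replication genes, 17 rose, none fell and 26 did not pass (21 rose when adjusted over the list alone). UHRF1, which maintains DNA methylation at replication, rose 1.98-fold, cyclin E2 (CCNE2) 2.00-fold and the helicase subunit MCM4 1.68-fold, the last on all of its 4 tested probe sets. Of 45 measured mitosis genes, 14 fell, 1 rose and 30 did not pass (18 fell and 1 rose when adjusted over the list alone). CDC20 fell from 431.8 ± 104 to 109 ± 9.97 (SD, n = 2), cyclin B1 (CCNB1) fell 1.99-fold, the kinesin KIF20A 2.03-fold and the ubiquitin-conjugating enzyme UBE2C 1.78-fold. The gene that rose was the condensin subunit SMC2 (log2 fold change 0.40), named after its value was seen, a call lost without hypoxia replicate 1, hypoxia replicate 2 or normoxia replicate 2 (adjusted p = 0.242, 0.142 and 0.108). Medians of the log2 fold change were 0.37 for DNA replication (camera, adjusted p = 2.83e-12) and -0.24 for mitosis (adjusted p = 6.25e-05). In the test with an estimated correlation, the adjusted p was 0.416 for DNA replication and 0.513 for mitosis. Without hypoxia replicate 1, 5 replication genes rose and 6 mitosis genes fell, and without hypoxia replicate 2 these numbers were 6 and 5, while both lists stayed past the threshold.

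Of 8 measured replication-dependent histone genes, 3 fell, none rose and 5 did not pass (5 fell when adjusted over the list alone). H2AC6 fell 2.59-fold, H1-2 2.19-fold and H2BC5 1.80-fold, the last losing its call without hypoxia replicate 1 (adjusted p = 0.0596), where 2 fell. The median log2 fold change of the list was -0.36 (camera, adjusted p = 0.00546), with an adjusted p = 0.513 with an estimated correlation. Histone genes resemble one another closely, so these probe sets may share signal. Among 19 measured genes of homologous recombination and mismatch repair, 3 rose and none fell (3 also when adjusted over the list alone), EXO1 (1.87-fold), FANCI (1.33-fold) and MSH6 (1.25-fold). None of the 3 kept its call without hypoxia replicate 1 (adjusted p = 0.0842, 0.169 and 0.187) or hypoxia replicate 2 (0.0580, 0.179 and 0.212). FANCI and MSH6 also lost it without normoxia replicate 1 (0.0719 and 0.0956), and MSH6 without normoxia replicate 2 (0.0595) or over the mean of its probe sets (0.13, 0.597). That list did not pass (camera, adjusted p = 0.0862, and 0.546 with an estimated correlation), but did with the mean of probe sets (0.0480). It passed in no other alternative. Of 21 measured p53 targets, DDB2 rose 1.90-fold and TIGAR fell 1.66-fold (1 and 1 when adjusted over the list alone), and the cell cycle inhibitor CDKN1A had a log2 fold change of 0.37 (adjusted p = 0.0803). DDB2 and TIGAR lost their calls without hypoxia replicate 1 (adjusted p = 0.0552 and 0.0648), TIGAR also without hypoxia replicate 2 (0.0506), and the p53 list did not pass (camera, adjusted p = 0.777).

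Most measured cholesterol synthesis genes rose. Of 20 measured genes of cholesterol synthesis and its control, 12 rose, none fell and 8 did not pass (14 rose when adjusted over the list alone). HMGCS1, which makes the precursor HMG-CoA, rose 2.75-fold, the sterol methyl oxidase MSMO1 1.89-fold and squalene epoxidase SQLE 1.62-fold, the last on 2 of its 4 tested probe sets. INSIG2, which restrains sterol synthesis, rose 2.64-fold. The list had a median log2 fold change of 0.51 (camera, adjusted p = 7.22e-10), with an adjusted p = 0.386 with an estimated correlation. The number that rose was 7 without hypoxia replicate 1 and 6 without hypoxia replicate 2. On the list for fatty acid synthesis and desaturation, the desaturase SCD rose 2.70-fold, the only call among 15 measured genes (1 also when adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.472). The carboxylase ACACA, at -1.58 (adjusted p = 0.0785), differed between the hypoxic arrays (signals of 137.7 and 29.6), with -2.46 without hypoxia replicate 1 (adjusted p = 0.00973) and -0.71 without hypoxia replicate 2 (0.155). It also passed with median centring (7.81e-04) and the replicate block (3.15e-04). Of 15 measured genes of serine and one-carbon metabolism, 3 rose and none fell (3 and 1 when adjusted over the list alone), among them methionine synthase MTR (1.94-fold) and thymidylate synthase TYMS (1.58-fold). The other, the serine synthesis enzyme PSAT1 (1.40-fold), lost its call without hypoxia replicate 1 (adjusted p = 0.214), hypoxia replicate 2 (0.119), normoxia replicate 1 (0.0839), where 2 rose and 1 fell, or normoxia replicate 2 (0.102). That list did not pass (camera, adjusted p = 0.962), with a median of -0.08, a mean of 0.03 and a test direction above 0.

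Some heat shock proteins fell, whereas some genes of the endoplasmic reticulum and of the integrated stress response rose. Of 16 measured heat shock proteins and cytosolic chaperones, 8 fell, none rose and 8 did not pass (8 fell also when adjusted over the list alone). HSPH1 fell from 1179 ± 60.7 to 298 ± 14.6 (SD, n = 2) and the chaperonin subunit CCT3 fell 1.68-fold. Of 27 measured endoplasmic reticulum chaperones and unfolded protein response genes, 8 rose, 1 fell and 18 did not pass (12 rose and 4 fell when adjusted over the list alone). The oxidase ERO1A rose 2.40-fold and the disulfide isomerase P4HB 1.82-fold, and the gene that fell was DNAJB11 (log2 fold change -0.49). Of 29 measured targets of ATF4 and the integrated stress response, 9 rose, 1 fell and 19 did not pass (11 rose and 2 fell when adjusted over the list alone). DDIT4, an inhibitor of the growth kinase mTORC1, rose 5.66-fold. The transcription factors ATF5 and ATF3 rose 2.76-fold and 1.80-fold, and the amino acid transporter SLC7A5 1.99-fold. The gene that fell was CEBPG (-0.53). Its value was 0.21 without hypoxia replicate 1 and 0.0059 without normoxia replicate 2. For a fixed probe set, the values without either array of a group average to the full value. Those of CEBPG do not, so some of these fits read another of its probe sets. DNAJB11 and CEBPG were named after their values were seen. Median log2 fold changes were -0.43 for heat shock proteins (camera, adjusted p = 1.24e-04), 0.28 for the endoplasmic reticulum list (1.33e-04) and 0.25 for the ATF4 list (2.25e-04). None of the 3 lists passed with an estimated correlation (adjusted p = 0.416, 0.386 and 0.386 in the same order). Without hypoxia replicate 1, 2 heat shock proteins fell, 2 endoplasmic reticulum genes and 4 ATF4 targets rose, and without hypoxia replicate 2 the numbers that rose were 2 and 5. DNAJB11 lost its call without hypoxia replicate 1, hypoxia replicate 2 or normoxia replicate 2, at log2 fold changes of -0.39, -0.59 and -0.37. CEBPG lost its call without any 1 of the 4 arrays, where some fits read another of its probe sets.

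**Figure D3:**
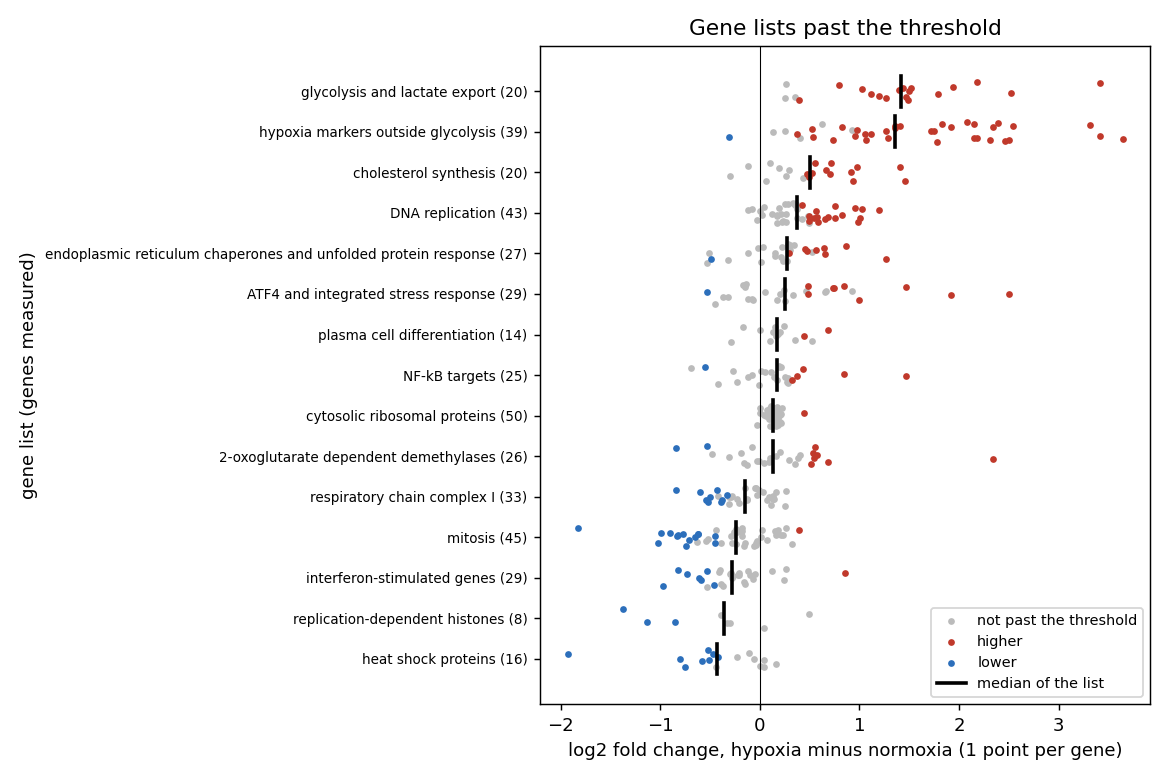
Log2 fold change of hypoxia over normoxia (horizontal axis, log2 units) of each measured gene on the 15 lists past the threshold (vertical axis, with the number of genes measured). Red points rose, blue points fell, grey points did not pass, and black bars mark list medians, which run from 1.42 for glycolysis to -0.43 for heat shock proteins.

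Few genes for growth and translation passed the test. P493-6 cells carry a MYC transgene that tetracycline represses, and the labels do not say whether it was on in these cultures, which bears on every value for MYC and its targets. MYC had a log2 fold change of -0.37 ± 0.17 (SE, limma, adjusted p = 0.207) with normoxic signals that lay far apart (1122 ± 303, SD, n = 2), and its value was -0.65 without normoxia replicate 1 (adjusted p = 0.00816) and -0.10 without normoxia replicate 2 (adjusted p = 0.708). Among the other alternatives it passed only with the replicate block (adjusted p = 0.00661). Of 9 measured genes of the MYC network, MXI1 alone passed (1 rose and 1 fell when adjusted over the list alone, as without normoxia replicate 1), and the list did not (camera, adjusted p = 0.792). Of 41 measured genes of ribosome biogenesis and MYC targets, 4 rose and none fell (6 and 2 when adjusted over the list alone), led by the purine synthesis enzyme PAICS (2.01-fold). That list did not pass (camera, adjusted p = 0.472), with a median of -0.0029, a mean of 0.01 and a test direction above 0. The number that rose was 1 without hypoxia replicate 1, 2 without hypoxia replicate 2, 6 without normoxia replicate 2, and 2 without normoxia replicate 1, where 3 fell. Of 27 measured proteasome subunits, PSMB5 fell 1.33-fold (none when adjusted over the list alone), a call lost without any 1 of hypoxia replicate 1, hypoxia replicate 2, normoxia replicate 1 and normoxia replicate 2 (adjusted p = 0.0529 to 0.264). The proteasome list did not pass (camera, adjusted p = 0.413), but did without normoxia replicate 1 (0.0383, within a range of 0.0383 to 0.950 over the alternatives), where PSMB6 (0.0182) and PSMA7 (0.0276) fell, as they did with median centring (0.0446 and 0.0490), quantile normalization (0.0437 and 0.0428) or the filter at the 75th percentile (0.0409 and 0.0446), in 6 and 5 of 14 alternatives in all, with adjusted p-values of up to 0.271 and 0.292 in the others.

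Of 50 measured cytosolic ribosomal proteins, RPL35A passed, with a rise of 1.36-fold (none when adjusted over the list alone). It lost its call in 9 of 14 alternatives, among them quantile normalization (limma, adjusted p = 0.616) and the mean of its probe sets (0.08, 0.599). The call was also lost without hypoxia replicate 1 (log2 fold change 0.16), hypoxia replicate 2 (0.17) or normoxia replicate 1 (0.29). Without a hypoxic array, another of its probe sets, at 0.17 with all arrays, was the brightest. The list passed with a median log2 fold change of 0.14 (camera, adjusted p = 1.81e-07), with an adjusted p = 0.727 with an estimated correlation. Under quantile normalization the median was 0.01 (adjusted p = 0.608, within a range of 1.07e-14 to 0.608 over the alternatives). The actin control probe sets, with mean signals of 12264 to 14382, differed by 0.13 to 0.14 in the same direction.

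B cell genes moved both ways. Of 30 measured genes on the B cell identity list, 8 fell and 2 rose (9 and 4 when adjusted over the list alone). The surface protein CD24 fell 2.43-fold, with all of its 6 tested probe sets past the threshold, the transcription factor IKZF1 fell 1.69-fold and PAX5, which holds B cell identity, fell 1.53-fold. TCF3 rose 1.72-fold, on 2 of its 12 tested probe sets. Its call was lost without hypoxia replicate 1 (log2 fold change 0.31) or hypoxia replicate 2 (0.51). There another of its probe sets, at 0.41 with all arrays, was the brightest, so the loss is not an effect of the array alone. Fewer genes of the list passed in both fits. The list did not pass (camera, adjusted p = 0.0798), but did in 7 of 14 alternatives, which were without hypoxia replicate 1 (0.0235), without normoxia replicate 2 (0.0244), an offset of 1 (0.0474), no filter (0.0399), median centring (0.0371), quantile normalization (0.0184) and the replicate block, within a range of 0.0184 to 0.188. Of 8 measured germinal centre genes, S1PR2 rose 1.96-fold, ELMO1 rose 1.63-fold and LMO2 fell 1.68-fold (4 rose and 1 fell when adjusted over the list alone). ELMO1 and LMO2 lost their calls without hypoxia replicate 1 (adjusted p = 0.0683 and 0.0588), LMO2 also without hypoxia replicate 2 (0.0714). That list did not pass (camera, adjusted p = 0.0789), but did without normoxia replicate 1 and with no filter (0.0399), and in no other alternative. Without normoxia replicate 1, BACH2 rose as well (log2 fold change 0.62). BACH2 also passed with the filter at the 75th percentile (limma, adjusted p = 0.0448) and with the replicate block, and in no other alternative.

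Of 14 measured plasma cell differentiation genes, 2 rose and none fell (3 rose when adjusted over the list alone), PRDM1, which drives that differentiation (1.60-fold), and DERL3 (1.36-fold). PRDM1 lost its call without hypoxia replicate 1, hypoxia replicate 2 or normoxia replicate 2 (adjusted p = 0.210, 0.0565 and 0.0980) or over the mean of its probe sets (0.39, 0.116), and DERL3 lost it without the same arrays and also without normoxia replicate 1 (0.0559 to 0.227 over these). Over the whole list, the median log2 fold change was 0.17 (camera, adjusted p = 0.0112), with an adjusted p = 0.416 with an estimated correlation. It lost its call when arrays were centred on their medians (0.0542, within a range of 0.00536 to 0.0542 over the alternatives).

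Immune signalling genes showed modest differences. Of 29 measured interferon-stimulated genes, 7 fell and 1 rose (15 and 2 when adjusted over the list alone). IFI44L fell 1.77-fold and the exonuclease ISG20 rose 1.81-fold. The membrane restriction factor BST2 fell 1.96-fold, a call lost without hypoxia replicate 1 (adjusted p = 0.0570). The median log2 fold change of the list was -0.28 (camera, adjusted p = 1.80e-04), with an adjusted p = 0.669 with an estimated correlation. The number that fell was 1 without hypoxia replicate 1, 3 without hypoxia replicate 2, 9 without normoxia replicate 1 and 4 without normoxia replicate 2, and 2 rose in each of the last 2 fits. Of 25 measured NF-kB targets, 5 rose and 1 fell (7 and 2 when adjusted over the list alone), among them the chemokines CCL4 (2.76-fold higher) and CXCL10 (1.47-fold lower). That list had a median of 0.17 (camera, adjusted p = 0.0354), with an adjusted p = 0.711 with an estimated correlation. It lost its call in 7 of 14 alternatives, which were without hypoxia replicate 1 (0.120), without normoxia replicate 1 (0.116), the filter at the 75th percentile (0.0698), median centring (0.102), quantile normalization (0.0793), no variance trend (0.132) and the mean of probe sets (0.0766), within a range of 0.0112 to 0.132. None of its genes was called without hypoxia replicate 1 or hypoxia replicate 2, and 2 rose and 2 fell without normoxia replicate 1. Of 23 measured antigen presentation genes, TAP2 (1.40-fold) and PSMB9 (1.26-fold) fell and HLA-E rose 1.25-fold (2 fell and 3 rose when adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.483). All 3 lost their calls without hypoxia replicate 1 (adjusted p = 0.0786, 0.110 and 0.0937) or hypoxia replicate 2 (0.0745, 0.133 and 0.0919), and PSMB9 and HLA-E also without normoxia replicate 1 (0.0562 and 0.0623) or normoxia replicate 2 (0.0636 and 0.0634).

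Among regulators of cell survival, BCL2 rose 1.76-fold and MCL1, another inhibitor of apoptosis, fell 1.61-fold. Of 18 measured BCL2 family members, 4 rose and 1 fell (4 and 2 when adjusted over the list alone). BCL2 passed on 1 of its 4 tested probe sets, and it lost its call over the mean of them (0.52, limma, adjusted p = 0.0718) or without hypoxia replicate 1 (0.0645), where 2 members rose. The list did not pass (camera, adjusted p = 0.263, and 0.759 with an estimated correlation). It passed without normoxia replicate 2 and in no other alternative. Its median was -0.01 with a mean of 0.25 and a test direction above 0. Of 29 measured autophagy and mitophagy genes, BNIP3 and BNIP3L rose, and ATG3 (1.42-fold) and LAMP1 (1.28-fold) fell (2 and 2 when adjusted over the list alone). ATG3 and LAMP1 lost their calls without hypoxia replicate 1 (adjusted p = 0.124 and 0.0698) or hypoxia replicate 2 (0.0925 and 0.209), and LAMP1 also without normoxia replicate 2 (0.112), where 3 rose and 1 fell, or over the mean of its probe sets (-0.23, 0.212). That list did not pass (camera, adjusted p = 0.889), with a median of -0.09, a mean of 0.05 and a test direction below 0.

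Of 26 measured 2-oxoglutarate-dependent demethylases, which use oxygen as a substrate, 7 rose and 2 fell (8 and 3 when adjusted over the list alone). The histone demethylase KDM3A rose from 528 ± 70.2 to 2724 ± 13.7 (SD, n = 2) and PHF2 fell 1.79-fold. KDM4B rose 1.60-fold, a call lost without hypoxia replicate 2 (adjusted p = 0.0504). The list had a median log2 fold change of 0.13 (camera, adjusted p = 0.0269), with an adjusted p = 0.546 with an estimated correlation. It lost its call without hypoxia replicate 2 (0.145) and with the mean of probe sets (0.0683), within a range of 0.0144 to 0.145 over the alternatives. Of its members, 1 rose and 1 fell without hypoxia replicate 2, and 2 rose and 1 fell without hypoxia replicate 1.

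Markers of other cell types and controls of RNA quality were examined as well. Of 6 measured T cell markers none passed, also when adjusted over the list alone, and CD2 had a log2 fold change of -0.66 (-0.95 to -0.37 over the alternatives, past the threshold in 2 of 13, median centring and the replicate block, limma, adjusted p = 0.0429 for each) and CD3E of -0.37. Of 9 measured myeloid markers, the integrin ITGAM fell 1.80-fold and lysozyme LYZ 1.98-fold (2 also when adjusted over the list alone), LYZ losing its call without hypoxia replicate 2 (limma, adjusted p = 0.0602) and ITGAM over the mean of its 2 probe sets (-0.46, 0.0982), of which 1 passed. Of 9 measured fibroblast, epithelial and endothelial markers, ACTA2 fell 2.01-fold and PECAM1 rose 1.63-fold (1 and 1 when adjusted over the list alone), PECAM1 losing its call without hypoxia replicate 1 (limma, adjusted p = 0.0737), hypoxia replicate 2 (0.0916) or over the mean of its probe sets (0.44, 0.0838). The lists did not pass (camera, adjusted p = 0.844 for T cell, 0.739 for myeloid and 0.962 for the other markers, the last with a median of 0.03, a mean of -0.08 and a test direction below 0). The control probe sets for the 5′ and 3′ parts of actin gave log2 differences of 0.14 and 0.14 between hypoxia and normoxia, and those of GAPDH gave 0.42 and 0.49, outside the test.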

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

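The 50% of probe sets with the lowest mean signal were left out of the test. When all probe sets were tested (limma), 2 of them rose under hypoxia and none fell, with 1045 higher and 809 lower at an unadjusted p under 0.05. The first reads STC2, which encodes stanniocalcin 2, a secreted glycoprotein, with a signal of 7.25 ± 0.78 in normoxia and 99.3 ± 0.71 in hypoxia (SD, n = 2; log2 fold change 2.31, limma, adjusted p = 0.0356). A brighter probe set of STC2 was part of the main test and rose too (log2 fold change 1.92), a call lost without hypoxia replicate 1 (adjusted p = 0.0671). The second carries no gene name in the annotation used here and went from 2.35 ± 1.34 to 81.5 ± 2.97 (SD, n = 2; log2 fold change 2.41, limma, adjusted p = 0.0328). Both normoxic signals are near the bottom of the scale, so both folds depend on the offset of 16. No explanation was tested for either.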

How the results depend on the processing

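The fit without _x_at probe sets and the mean of probe sets for single named genes were chosen after the data were seen. The counts of calls depended on the model of variance more than on the scaling. The number of changed probe sets (1801) was 715 with no filter, 170 with no intensity trend and 3756 with the replicate number as a block, and the number of changed genes (1385) was 793, 187 and 2576 in the same settings. All 1385 genes were among those called with the block, and 186 of the 187 called without the trend were among them. The labels give no basis for the pairing, and the deviations of arrays with the same number correlated at 0.111, so the block's count is given here alone. Leaving out each array in turn gave 364 to 1592 probe sets, 380 to 1312 genes and 14 to 18 of the 36 lists. The fits without a hypoxic array gave the low end, 364 probe sets without hypoxia replicate 1 and 394 without hypoxia replicate 2. In these fits the spread rests on the normoxic arrays alone. The median absolute log2 difference was 0.185 between the normoxic arrays and 0.167 between the hypoxic arrays. Whether this accounts for the lower counts was not tested. The split of probe sets into higher and lower moved from 851 and 950 to 666 and 1180 with median centring, to 428 and 287 with no filter and to 128 and 42 without the trend, and more were higher than lower without any 1 of the arrays. The 15 lists became 0 with an estimated correlation, where camera gave 4 lists an unadjusted p under 0.05. That test rests on 2 residual degrees of freedom. Without this setting, 10 of the 15 lists passed under every alternative run, and no called list, and no called gene chosen by the fixed rule, reversed its direction under any. CEBPG, named outside that rule and run only with arrays left out, was at -0.53 with all arrays. It was at 0.21 without hypoxia replicate 1 and at 0.0059 without normoxia replicate 2. Some of its fits read another probe set, so the change of sign cannot be laid to an array. Of 120 named genes past the threshold, 46 stayed past it in every alternative in which they were measured; 71 lost it without the trend, 50 without hypoxia replicate 1 and 43 without hypoxia replicate 2. Offsets of 1 and 64, quantile normalization, the filter at the 75th percentile, median centring and the fit without _x_at probe sets left the counts of probe sets, genes and lists within 1.5 times, as did the mean of probe sets for genes and lists.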

Other observations

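Of the tests below, some were planned. These were the limma fit, camera with an estimated correlation, the fits with an array left out, the comparisons with lists matched on signal and the count of other splits. All other tests below were chosen after the results were seen, as was the group of long non-coding RNAs.

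Long non-coding RNAs were a small part of the response. Of 823 tested, 12 rose and 8 fell, a smaller share than the 11.2% called among all tested genes. Why the share was smaller was not tested. The long non-coding RNAs named here were chosen after their values were seen. MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210, rose 5.52-fold, from 155 ± 34.0 to 918 ± 11.2 (SD, n = 2; limma, adjusted p = 1.14e-04). LINC00158 rose 2.49-fold, EPB41L4A-AS1 2.36-fold and ZFAS1, which hosts small nucleolar RNAs, 1.53-fold, while ATP8B1-AS1 fell 2.15-fold. Without hypoxia replicate 1, 6 rose and 5 fell, without hypoxia replicate 2, 4 rose and 1 fell, without normoxia replicate 1, 16 rose and 5 fell, and without normoxia replicate 2, 18 rose and 8 fell. These 5 genes passed in each of these fits.

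The number of changed probe sets was 1801 for the real grouping of the 4 arrays. The 3 possible splits, of which 1 gave as many, are too few for a share under 0.05. The highest of the other splits gave 0 probe sets (limma, 656 and 312 at an unadjusted p under 0.05, against 5961 in the real grouping). Each other split joins 1 hypoxic with 1 normoxic array, so a difference between the groups widens its spread and lowers its count. The 0 is therefore no measure of how many calls arise without such a difference.

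Of 43 DNA replication genes 17 rose and 26 did not pass, and of 45 mitosis genes 14 fell, 1 rose and 30 did not pass. Neither list passed with an estimated correlation (camera, adjusted p = 0.416 and 0.513). Against signal level as the whole cause, the replication median of 0.37 lay above the central 95% of 10000 random lists matched on signal (-0.15 to 0.07), and the mitosis median of -0.24 lay below it (-0.15 to 0.05). A shift of cells from mitosis towards the start of DNA synthesis may account for both and stays open, since no cell cycle measurement was analysed here. The replication-dependent histones, which peak in S phase, had a median of -0.36, but an oligo-dT primer reads their mostly unpolyadenylated transcripts poorly.

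HIF1A fell while most hypoxia markers rose. Lower RNA integrity in the hypoxic cells is argued against by the control probe sets. Their difference of 5′ and 3′ signals changed by -0.0062 for actin and -0.063 for GAPDH on the log2 scale, against -1.43 for HIF1A. These signals lie near the highest on the arrays (actin means of 12264 to 13770, array maxima of 15755 to 17877). Differences may be compressed there, which limits this check. A fault of the HIF1A probe set cannot be told apart from a true fall, because only 1 probe set names the gene. A fall of the transcript during long hypoxia is a candidate biological explanation and was not tested.

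Of 20 cholesterol synthesis genes 12 rose and 8 did not pass, and the list did not pass with an estimated correlation (camera, adjusted p = 0.386). A candidate explanation is that the enzymes that use oxygen responded most. The 3 of them that were measured (SQLE, MSMO1 and SC5D) had a mean log2 fold change of 0.70 against 0.51 for the 17 other members, a difference of 0.19 with p = 0.522 (exact two-sided permutation test of membership across genes, which are not independent replicates). SC5D lost its call without hypoxia replicate 1 (limma, adjusted p = 0.203), hypoxia replicate 2 (0.141), normoxia replicate 1 (0.130) or normoxia replicate 2 (0.0646). With so few genes the explanation cannot be told apart from an equal response of all members.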
